A study of Arabidopsis thaliana with 8 samples.

How the data were processed

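Roots of Arabidopsis thaliana Col-0 seedlings, wild type and bzr1-D, were grown on MS medium with 0.2% sucrose at 22 °C under 16 h light and 8 h dark, and moved at day 6 to adequate (0.625 mM) or low (1 µM) Pi for 24 h before the roots were harvested, per the labels' protocols. Polyadenylated RNA was sequenced as 50-base single reads on an Illumina HiSeq instrument, per the labels' protocols. The data were 1 table of read counts per annotated feature for 8 libraries, deposited by the authors as whole-number counts with no normalization. TopHat2 2.0.11, HTSeq 0.6.1 and DESeq2 1.2.8 and the TAIR10 annotation are named, per the submitters' processing notes, with no order or settings. The strand setting and the treatment of reads that map to several places are not given in the sources used here. HTSeq by default drops reads that overlap 2 features or map to several places, which would lower the counts of overlapping genes and of near-identical copies. Genes that overlap a neighbour were therefore treated as uncertain.

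Groups came from the labels, which name genotype, Pi supply and an Exp number. In the labels, the values for strain and tissue stand under each other's tag, and the sample titles were used to settle the genotype. Each of the 4 groups held 2 libraries described as biological replicates. The table held 40246 features, of which 32940 were matched to a locus of the reference annotation of TAIR10.1 by locus identifier. For 99.8% of the matched genes the start lay within 2 kb of the reference. Coordinates are those of the deposited table. Some loci stood in the table more than once or under a transcript identifier, 113 features in all sharing a locus, and they were tested as given.

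The total counts per library were 19526263 and 22150569 in wild type at adequate Pi, 17902669 and 18076216 in wild type at low Pi, 19486426 and 15947895 in bzr1-D at adequate Pi and 20063436 and 18212668 in bzr1-D at low Pi. A gene at 1 CPM therefore rested on at least 15.9 counts. A group at 0 was given as a bound against a floor of 3 counts per library, which covers counting error only, as PCR copies cannot be told from separate molecules. Replicates were compared by a chi-square test of their counts, and chi-square per degree of freedom lay between 17.6 and 38.0 in the 4 groups, so in none of them was a library a copy of the other.

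Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (robust fit) with 1 coefficient per group over all 8 libraries, TMM scaling and the default filter on low counts (minimum count 10), which left 20262 features. Residual degrees of freedom were 4. P-values were adjusted with Benjamini-Hochberg over all features tested in a comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F value. CPM values are per library, scaled by TMM, and given as mean ± SD. The 5 comparisons were the Pi response in each genotype, the genotype difference at each Pi supply and the difference of the Pi responses. The pooled biological coefficient of variation was 0.169, and 0.0858 with the Exp number in the fit.

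The Exp numbers come from the labels, which do not say what libraries with the same number share. Whether they pair the libraries was checked on the deviations from the group means. In each of the 6 pairs of groups, same-numbered libraries deviated together (correlations from 0.29 to 0.64), and a principal component with 19.6% of the variance separated the numbers. The numbers were therefore taken to pair the libraries. Values with the replicate block are given for the counts of genes called in each comparison, and for a part of the single genes and lists. The fit without the block stayed the reported one, as chosen before the data were examined. It counts any shift between the Exp numbers as spread within groups, so a gene without a call there may still differ.

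Before the data were examined, 17 gene lists were fixed. They cover Pi transport and sensing, phosphatases and nucleases, membrane lipid remodelling, local Pi sensing, iron deficiency, iron storage, brassinosteroid synthesis (with inactivation), brassinosteroid perception, growth genes raised by brassinosteroid, auxin, root hairs, the root meristem, suberin, flavonoids, nitrate uptake, shoot tissue and touch. Of 277 members, 7 were left out because name and locus did not match in the reference, 28 had too few counts and 242 were tested. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and with fry. With the estimated correlation, the calls that held were those of the 3 Pi lists in bzr1-D. Camera compares a list with the other genes, whereas fry asks whether its members move one way on balance. Counts of members are also given adjusted over the list alone.

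Genes were named by a rule fixed before the data were examined. In each comparison it takes BZR1, BRI1, BKI1, LPR1 and LPR2, the 6 called genes with the largest change in each direction with a mean log2 CPM of at least 1 and the same sign within both Exp numbers, and per list up to 4 called members or else up to 2 with the smallest p. Not every gene that this rule selects is reported here. Genes named for a call with the replicate block, members named for a call adjusted over the list alone, and genes named for their place outside the chromosome blocks were chosen after their values were seen.

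Alternatives fixed before the data were examined were other size factors, other filters on low counts, DESeq2 1.42.0, limma-voom, only the libraries compared, the Exp number as replicate block, stricter thresholds and each library left out in turn. Where a left-out library leaves a group with 1 library, that library is assumed to vary like the other groups. Chromosome blocks were runs of windows of 1 Mb with at least 2 genes called at both Pi levels, with at most 2 other windows between them. The chance spread of calls over windows was taken from 10000 random draws of tested genes. Shared sequence between PHT1 genes was measured as the share of 50-base stretches of their exons in the reference that occur in the other gene.

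The procedure was tested on simulated counts with the real means and library sizes and 200 of 20262 genes changed. For the Pi response in wild type with a simulated batch effect, 33% of 2-fold and 88% of 4-fold changes were called without the block, with 1 false call, and 91% and 98% with the block, with 29 false calls. For the genotype difference at adequate Pi these shares were 35% and 89% with 0 false calls, and 85% and 100% with 28 false calls. For the difference of the Pi responses they were 3% and 71% with 0 false calls, and 72% and 97% with 19 false calls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.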

Results

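Roots of Arabidopsis thaliana seedlings of the Col-0 accession were profiled by sequencing of polyadenylated RNA in 4 groups of 2 libraries. Wild type and bzr1-D were each moved at day 6 to medium with adequate phosphate (Pi, 0.625 mM) or low Pi (1 µM) and harvested 24 h later. The bzr1-D line carries a dominant gain-of-function allele of BZR1, a transcription factor at the end of the brassinosteroid signalling pathway. Brassinosteroids are steroid hormones that promote growth. The labels give the 2 libraries of each group as biological replicates, numbered as experiment (Exp) 1 and 2. Total counts per library ranged from 15947895 to 22150569, so that a level of 1 CPM (1 count per 1000000 counts) stood for at least 15.9 counts. Of 40246 features in the table, 20262 held enough counts to be tested.

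BZR1 (AT1G75080.1, chromosome 1, 28185504 to 28187410) was measured first as a view of the genotype. Its level was 29.2 ± 1.55 CPM (SD, n = 2) in wild type at adequate Pi and 32.4 ± 0.579 CPM at low Pi. In bzr1-D it was 31.3 ± 3.65 CPM (SD, n = 2) at adequate Pi and 29.0 ± 1.59 CPM at low Pi. The log2 fold change between genotypes was 0.10 ± 0.12 (SE) at adequate Pi and -0.16 ± 0.12 at low Pi. Adjusted p was 1.00 and 0.80 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The allele acts through the protein, so the transcript level does not check the genotype labels.

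The first comparison asked how wild-type roots answered 24 h at low Pi. SPX1, an intracellular Pi sensor, went from 7.61 ± 0.235 CPM (SD, n = 2) at adequate Pi to 58.7 ± 42.1 CPM at low Pi, a log2 fold change of 2.95 ± 0.56 (SE). It was 1.94 within Exp 1 and 3.49 within Exp 2. PAP17, a purple acid phosphatase, went from 7.32 ± 0.327 to 31.1 ± 17.9 CPM. GDPD2, which breaks down glycerophosphodiesters left by phospholipid turnover, rose with the Exp number as replicate block (0.66 ± 0.12 log2, adjusted p = 0.032). PCK2, a phosphoenolpyruvate carboxykinase, went from 46.4 ± 0.904 to 96.3 ± 1.91 CPM (1.05 ± 0.10 log2, adjusted p = 0.26, and 9.4e-04 with the replicate block).

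The Pi transport and Pi sensing list rose as a group in wild type (19 members, median log2 fold change 0.67, adjusted p = 2.1e-15 by camera). Its adjusted p = 0.16 with an estimated correlation. Within Exp 1 and Exp 2 the medians were 0.65 and 0.86. Of its members, 12 rose adjusted over the list alone, and 5 with the replicate block, which were PHT1;1, PHT1;8, PHT1;9, PHF1 and SPX2. PHT1;8, a Pi transporter, was near the detection floor at adequate Pi (0.0674 CPM) and reached 1.22 ± 0.717 CPM (SD, n = 2) at low Pi. The list of phosphatases and nucleases rose (11 members, median 0.44, adjusted p = 4.3e-07, and adjusted p = 0.18 with an estimated correlation). PAP12, PAP17 and PS2 passed when adjusted over the list alone, and PAP12 with the replicate block. PS2, a phosphatase, went from 2.73 ± 0.365 to 7.43 ± 2.87 CPM. The membrane lipid remodelling list, whose enzymes replace phospholipids by galactolipids and sulfolipids, rose with a median of 0.19 (13 members, adjusted p = 4.3e-07, and adjusted p = 0.18 with an estimated correlation). GDPD1 (1.33 ± 0.28) and GDPD2 passed when adjusted over the list alone, and GDPD2 with the replicate block. Each of these 3 lists kept its call whichever of the 4 libraries compared was left out. GDPD1 and PAP17 each overlap a neighbouring gene, and the strand setting of the counting is not given in the sources used here.

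Over all genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower in wild type at low Pi. An unadjusted p under 0.05 was found for 331 genes, where chance alone gives 1013. DESeq2 called 28 genes higher and 0 lower, and limma-voom 0 and 0. With the replicate block, edgeR called 13 genes higher and 4 lower, and 1095 genes had an unadjusted p under 0.05. Genes called with the replicate block included CNGC19, a cyclic nucleotide-gated channel (2.75 ± 0.36, SE), and XTR6, an enzyme that rejoins xyloglucan chains of the cell wall (1.11 ± 0.20). CER4, a fatty acyl-CoA reductase, fell by 0.83 on the log2 scale, and XTH17, a xyloglucan endotransglucosylase/hydrolase, fell by 0.66. The 4 calls had adjusted p = 0.0058, 0.010, 0.029 and 0.032 by edgeR with the replicate block. These counts depended on single libraries. Without wild type low Pi replicate 1, edgeR called 10 genes higher, and 171 higher and 58 lower with the replicate block. The blocked fit called 7 and 3 without wild type adequate Pi replicate 1, 0 and 0 without wild type adequate Pi replicate 2, and 11 and 0 without wild type low Pi replicate 2.

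Markers of shoot tissue and of touch moved with the Pi lists in wild type. The shoot tissue list rose (13 members, median 0.67, adjusted p = 0.0015, and adjusted p = 0.42 with an estimated correlation), with medians of -0.28 within Exp 1 and 1.46 within Exp 2. The call was lost without wild type adequate Pi replicate 2 (adjusted p = 0.286) and turned to lower without wild type low Pi replicate 2 (0.374). LHCB1.1, a light-harvesting protein of leaves, averaged 0.324 ± 0.330 CPM (SD, n = 2) at adequate Pi and 2.87 ± 3.82 CPM at low Pi, with 0.557 and 0.165 CPM within Exp 1 and 0.0899 and 5.57 CPM within Exp 2. The list of touch and wounding genes rose (10 members, median 0.12, adjusted p = 0.0026, and adjusted p = 0.42 with an estimated correlation). Its call was lost without wild type adequate Pi replicate 1 (0.660) or wild type low Pi replicate 2 (0.105). TCH3, a calmodulin-like gene raised by touch, averaged 45.7 ± 48.1 CPM (SD, n = 2) at adequate Pi and 236 ± 184 CPM at low Pi. JAZ10, a repressor of jasmonate signalling, passed when adjusted over the list alone (2.07 ± 0.46).

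Among lists outside Pi metabolism, 3 fell in wild type at low Pi by camera. The iron deficiency list fell (26 members, median -0.28, adjusted p = 6.7e-04, and adjusted p = 0.42 with an estimated correlation), with medians of 0.07 within Exp 1 and -0.46 within Exp 2. BHLH38 and BHLH39, regulators of iron uptake, had log2 fold changes of -0.82 ± 0.41 and -0.49 ± 0.20 (SE) and did not pass. The call was lost without wild type adequate Pi replicate 2 (0.982) or low Pi replicate 2 (0.0539). The brassinosteroid synthesis list fell (14 members, median -0.15, adjusted p = 0.0021, and adjusted p = 0.18 with an estimated correlation), and lost its call without wild type adequate Pi replicate 2 (0.148). With the replicate block, BR6OX1, a brassinosteroid C-6 oxidase, and SOB7, which inactivates the hormone, fell adjusted over the list alone. The flavonoid list fell (8 members, median -0.34, adjusted p = 0.0022, and adjusted p = 0.47 with an estimated correlation), and lost its call without wild type adequate Pi replicate 1 (0.418) or low Pi replicate 2 (0.268). Its members CHS, F3'H, UGT78D2 and MYB12 fell with the replicate block, adjusted over the list alone. CHS is the first enzyme of the flavonoid pathway.

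The auxin and root hair lists rose in wild type at low Pi. The auxin list had a median of 0.13 (27 members, adjusted p = 0.0076, and adjusted p = 0.42 with an estimated correlation). It lost its call without wild type adequate Pi replicate 1 (0.696) and turned to lower without low Pi replicate 2 (0.859). The root hair list had a median of 0.24 (18 members, adjusted p = 0.0076, and adjusted p = 0.60 with an estimated correlation). Its call was lost without wild type low Pi replicate 1 (0.0536), adequate Pi replicate 2 (0.520) or low Pi replicate 2 (0.102). The other 7 lists did not pass. Camera gave an adjusted p of 0.582 for local Pi sensing (13 members), 0.218 for iron storage (6 members), 0.313 for brassinosteroid perception (15 members) and 0.848 for growth genes raised by brassinosteroid (13 members). It gave 0.580 for root meristem genes (19 members) and for suberin (11 members), and 0.400 for nitrate uptake (6 members). Left-out libraries gave calls for the root meristem list (higher at 2.9e-04 without wild type adequate Pi replicate 1, lower at 0.0041 without its replicate 2 and higher at 0.016 without low Pi replicate 2), for iron storage (0.021 without adequate Pi replicate 2) and for nitrate uptake (0.045 without adequate Pi replicate 1). ALMT1, a malate channel of the local Pi response, rose adjusted over the list alone with the replicate block (0.56 ± 0.21). LPR1 and LPR2, ferroxidases that act in root growth arrest at low Pi, had log2 fold changes of -0.25 ± 0.30 and 0.17 ± 0.12 (SE).

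**Figure D1:**
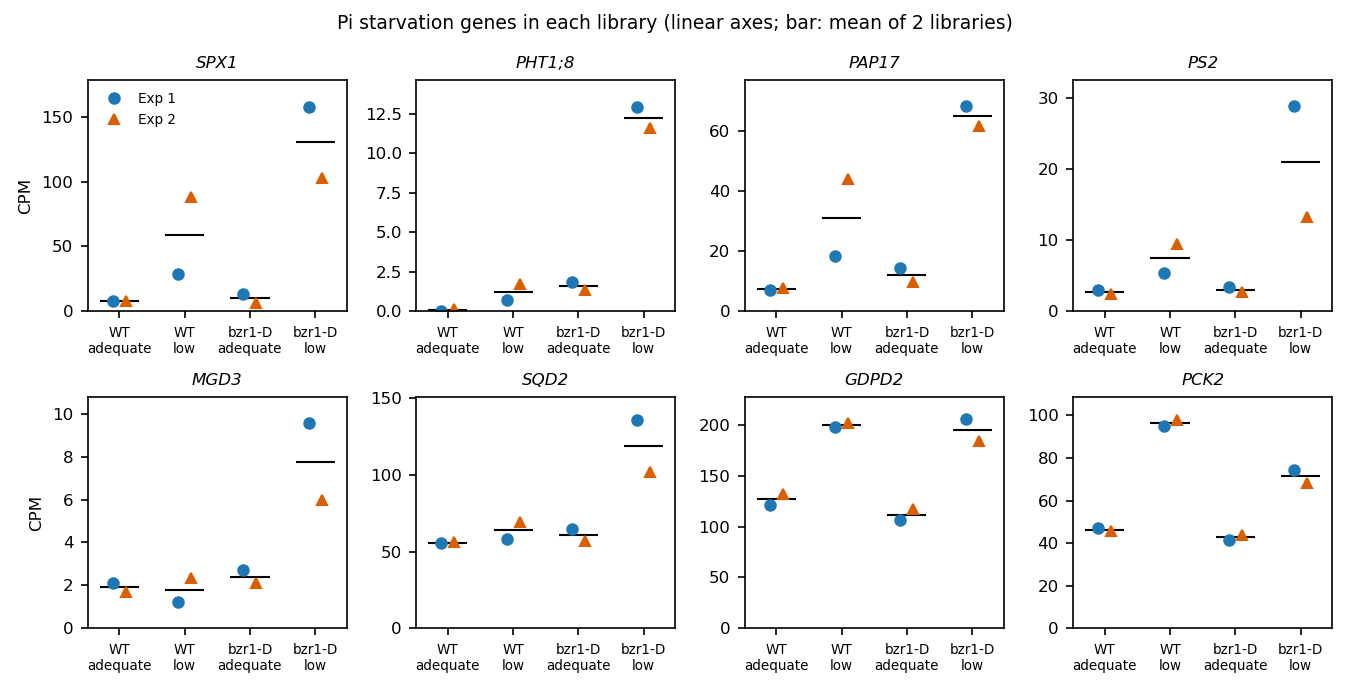
CPM of 8 genes in the 8 libraries, on axes that start at 0, with circles for Exp 1, triangles for Exp 2 and a line for the mean of 2 libraries. SPX1 averaged 58.7 CPM in wild type and 131 CPM in bzr1-D at low Pi, and MGD3 averaged 1.77 and 7.77 CPM.

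The same comparison in bzr1-D asked how roots with active BZR1 answered low Pi. SPX1 went from 9.90 ± 4.68 CPM (SD, n = 2) to 131 ± 38.7 CPM, a log2 fold change of 3.71 ± 0.57 (SE), with 3.57 within Exp 1 and 3.95 within Exp 2. PHT1;8 went from 1.62 ± 0.357 to 12.3 ± 0.942 CPM (2.91 ± 0.44 log2), PAP17 from 12 ± 3.22 to 64.9 ± 4.53 CPM (2.43 ± 0.39) and PS2 from 3.03 ± 0.420 to 21.0 ± 11 CPM (2.79 ± 0.43). SQD2, which makes sulfolipid, went from 61.0 ± 5.72 to 119 ± 23.6 CPM, and MGD3, a galactolipid synthase, from 2.41 ± 0.418 to 7.77 ± 2.52 CPM. GDPD1 went from 21.7 ± 1.28 to 80.8 ± 5.51 CPM. PHT1;8, GDPD2, PCK2 and UMAMIT38, a member of a family of amino acid transporters, rose with the replicate block (adjusted p = 0.043, 0.020, 0.020 and 0.020). Without it, edgeR's quasi-likelihood test gave adjusted p of at least 0.83 for each of them.

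All 3 Pi lists rose in bzr1-D by camera, and each kept its call with an estimated correlation (adjusted p = 0.041 for each). The call was lost with an estimated correlation and the replicate block together, where adjusted p was 0.13 for Pi transport, 0.18 for the phosphatases and 0.13 for lipid remodelling. The Pi transport list had a median log2 fold change of 0.86 (adjusted p = 2.6e-22), with 0.72 within Exp 1 and 1.25 within Exp 2. Of its 19 members, 11 rose adjusted over the list alone. The phosphatase list had a median of 0.59 (adjusted p = 2.6e-17). Its members PAP12, PAP17, PS2, PEPC1 and PPCK1 rose adjusted over the list alone, and 8 members with the replicate block. The lipid remodelling list had a median of 0.96 (adjusted p = 2.8e-27), with 1.06 within Exp 1 and 0.84 within Exp 2. Of its 13 members, 9 rose adjusted over the list alone. These were MGD2, MGD3, SQD1, SQD2, GDPD1, GDPD2, GDPD5 and the phospholipases PLDZ2 and NPC4.

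The root hair list rose in bzr1-D at low Pi (18 members, median 0.70, adjusted p = 1.9e-14, and adjusted p = 0.28 with an estimated correlation), and kept its call whichever of the 4 libraries compared was left out. COW1, which acts in root hair tip growth, had a log2 fold change of 0.92 ± 0.34 (SE), and EXPA7, an expansin of root hairs, 0.86 ± 0.35. The iron deficiency list fell (median -0.30, adjusted p = 2.5e-05, and adjusted p = 0.28 with an estimated correlation) and lost its call without bzr1-D low Pi replicate 2 (0.568). The iron storage list rose (median 0.24, adjusted p = 0.028, and adjusted p = 0.28 with an estimated correlation). It lost its call without bzr1-D low Pi replicate 1 (0.112), adequate Pi replicate 2 (0.415) or low Pi replicate 2 (0.239). With the replicate block, the suberin list (adjusted p = 0.034) and the touch list (adjusted p = 0.040) also rose by camera, and adjusted p was 0.53 for both with an estimated correlation and the replicate block. Without the block, the suberin list passed when bzr1-D adequate Pi replicate 1 (0.0097) or low Pi replicate 1 (0.043) was left out, and the touch list without adequate Pi replicate 1 (0.020). The flavonoid list was higher without adequate Pi replicate 1 (0.0097) or low Pi replicate 2 (0.011) and lower without adequate Pi replicate 2 (0.036). The root meristem list was lower without low Pi replicate 1 (1.1e-04) and higher without low Pi replicate 2 (0.011), and the nitrate uptake (0.031) and brassinosteroid synthesis (0.047) lists were lower without adequate Pi replicate 2. Over all genes, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, 253 genes had an unadjusted p under 0.05, DESeq2 called 20 and 0, and limma-voom 0 and 0. The replicate block gave 4 genes higher and 0 lower.

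**Figure D2:**
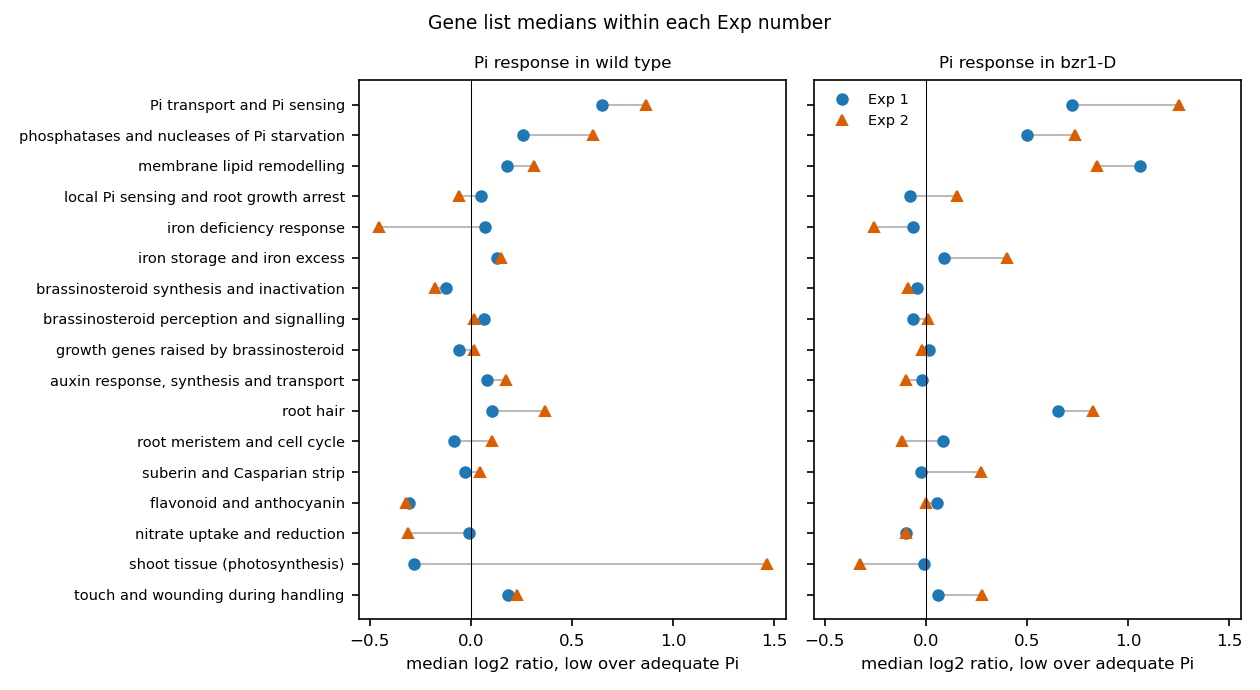
Median log2 ratio of low over adequate Pi over the members of each of the 17 gene lists, in wild type and in bzr1-D, with circles for Exp 1 and triangles for Exp 2. The membrane lipid remodelling list lies at 0.18 and 0.31 in wild type and at 1.06 and 0.84 in bzr1-D.

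The difference of the 2 Pi responses asked whether bzr1-D changed the answer to low Pi. Among the lists, the smallest p was that of membrane lipid remodelling, whose median response was higher by 0.55 on the log2 scale in bzr1-D (adjusted p = 7.5e-10 by camera, and adjusted p = 0.39 with an estimated correlation). It was 0.93 within Exp 1 and 0.21 within Exp 2, and the call was kept whichever of the 8 libraries was left out, with a median of 0.29 without wild type low Pi replicate 1. MGD3 responded more by 1.80 ± 0.53 (SE), SQD2 by 0.77 ± 0.23 and PS2 by 1.35 ± 0.60, with adjusted p of 1.00 for each by edgeR's quasi-likelihood test. With the replicate block, MGD2, MGD3, SQD2, PLDZ2 and GDPD5 responded more adjusted over the list alone. The phosphatase list also responded more in bzr1-D (median 0.28, adjusted p = 1.3e-04, and adjusted p = 0.41 with an estimated correlation). It lost its call without wild type low Pi replicate 1 (0.0787) or bzr1-D adequate Pi replicate 2 (0.0516). For the Pi transport list the difference was 0.05 (adjusted p = 0.035, and adjusted p = 0.43 with an estimated correlation), with adjusted p = 0.083 with the replicate block. It turned to lower without wild type low Pi replicate 1 (0.563). It lost its call without bzr1-D low Pi replicate 1 (0.154), wild type adequate Pi replicate 2 (0.292), bzr1-D adequate Pi replicate 2 (0.742) or bzr1-D low Pi replicate 2 (0.186).

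Over all genes, edgeR's quasi-likelihood test called 0 genes with a difference of Pi responses in either direction, with or without the replicate block. Unadjusted p was under 0.05 for 159 genes, and for 646 with the replicate block. DESeq2 called 0 and limma-voom 0, and DESeq2 with the replicate block called 1 gene higher. The blocked edgeR fit called 11 genes higher and 21 lower without wild type low Pi replicate 1. In simulated counts with a batch effect, 3% of 2-fold and 71% of 4-fold differences were called without the block, and 72% and 97% with it. False calls numbered 0 without the block and 19 with it.

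The Pi responses of the 2 genotypes used separate libraries. Across 20262 genes their log2 fold changes correlated with Pearson's r = 0.34 and Spearman's rho = 0.15, with a covariance of 0.0354. Genes are not independent replicates. Of the 100 genes with the smallest p in wild type, among them PCK2 and CNGC19, 80 had the same sign in bzr1-D. Of the 100 with the smallest p in bzr1-D, 91 had the same sign in wild type. Without a filter on low counts r was 0.060, and without 1 library at a time it ranged from 0.16 to 0.33. DESeq2 called 8 genes higher at low Pi in both genotypes. The replicate block gave 2 called in both, GDPD2 and PCK2.

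The second kind of comparison asked which genes differed between bzr1-D and wild type at the same Pi supply. At adequate Pi, BR6OX2 (AT3G30180, chromosome 3, 11810737 to 11813765), an enzyme of the last step of brassinosteroid synthesis, fell from 19.5 ± 1.19 CPM (SD, n = 2) in wild type to 9.73 ± 0.381 CPM in bzr1-D (adjusted p = 0.0096, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). MYB55, a MYB transcription factor, fell from 22.6 ± 1.23 to 3.37 ± 0.377 CPM (adjusted p = 1.8e-04). CLE2, a small signalling peptide, fell from 8.51 ± 1.57 to 1.82 ± 0.292 CPM. The Pi transporter PHT1;2 (AT5G43370, chromosome 5, 17415772 to 17417798) rose from 0.211 ± 0.0833 to 79.9 ± 17.8 CPM (adjusted p = 0.0025). Its neighbour PHT1;3 rose from 0.0253 to 3.98 ± 1.14 CPM (adjusted p = 0.0022) and PHT1;8 from 0.0674 to 1.62 ± 0.357 CPM (adjusted p = 0.035).

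In total, 143 genes were higher and 261 lower in bzr1-D at adequate Pi. DESeq2 called 220 and 411, and the replicate block gave 570 and 930. All 404 genes called without the block were also called with it. Left-out libraries lowered the counts to 74 and 147 (wild type adequate Pi replicate 1), 69 and 129 (wild type adequate Pi replicate 2), 69 and 116 (bzr1-D adequate Pi replicate 1) and 72 and 102 (bzr1-D adequate Pi replicate 2). Several of the most changed transcripts had 0 counts in 1 genotype. SADHU5-2, a retroelement, was at least 122-fold higher in bzr1-D, and AT5G35965 at least 67.9-fold higher. The pseudogene AT3G03855 was at least 164-fold lower (all 3 bounds against a floor of 3 counts per library). PHT1;8 lost its call with limma-voom (0.061), in a fit on only the libraries compared (0.067) and without any 1 of the 4 libraries, with adjusted p of 0.13 and 0.069 without wild type replicates 1 and 2 and 0.19 and 0.12 without bzr1-D replicates 1 and 2. CLE2 lost its call without bzr1-D adequate Pi replicate 2 (0.0593). BR6OX2 lost its call without bzr1-D adequate Pi replicate 1 (0.11), wild type adequate Pi replicate 2 (0.076) or bzr1-D adequate Pi replicate 2 (0.087).

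The brassinosteroid synthesis list fell in bzr1-D at adequate Pi (14 members, median -0.10, mean -0.48). Its adjusted p was 0.0048 by camera, 0.43 by camera with an estimated correlation and 0.042 by fry. Adjusted over the list alone, DWF4 (-1.01 ± 0.29, SE), CPD (-0.78 ± 0.18), CYP90D1 (-1.42 ± 0.28), BR6OX1 (-0.59 ± 0.18) and BR6OX2 (-1.0 ± 0.13) fell, all enzymes of the synthesis pathway. The Pi transport list rose (median 0.39, 0.70 within Exp 1 and 0.13 within Exp 2, adjusted p = 0.0048, and adjusted p = 0.75 with an estimated correlation), and lost its call without bzr1-D adequate Pi replicate 1 (0.0964). PHT1;1, the main root Pi transporter, fell adjusted over the list alone (199.9 ± 15.5 CPM in wild type and 114 ± 28.5 CPM in bzr1-D). Of the 50-base stretches of PHT1;2 exons, 45.1% also occur in PHT1;1, so their counts cannot be fully separated. The members called over all genes, PHT1;2, PHT1;3 and PHT1;8, lie in the chromosome blocks described below. The Pi transport list was not tested without them. The root hair list fell (median -0.71, adjusted p = 1.2e-04, and adjusted p = 0.75 with an estimated correlation) and lost its call without bzr1-D adequate Pi replicate 2 (0.123). RSL4 and LRL3, root hair regulators, fell with the replicate block (adjusted p = 0.023 and 0.0038).

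The shoot tissue list moved with these groups at adequate Pi. It was higher in bzr1-D (median 1.01, 0.76 within Exp 1 and 0.86 within Exp 2, adjusted p = 1.2e-04, and adjusted p = 0.75 with an estimated correlation), and LHCA3, a light-harvesting protein, rose adjusted over the list alone (0.89 ± 0.20, SE). LPR1, a ferroxidase that limits root growth at low Pi (AT1G23010, chromosome 1, 8147264 to 8149813), was at 11 ± 2.27 CPM in wild type and 6.16 ± 2.03 CPM in bzr1-D (adjusted p = 0.38), and fell with the replicate block (0.0036). The other 13 lists did not pass, with adjusted p from 0.0999 for the touch list to 0.855 for lipid remodelling. Without wild type adequate Pi replicate 1, the touch (0.0040), iron deficiency (0.0064) and root meristem (4.5e-04) lists passed, and without bzr1-D adequate Pi replicate 1 the touch (0.027) and flavonoid (0.0081) lists. BEE1, a growth regulator raised by brassinosteroid, had 1.04 CPM in wild type and 2.79 CPM in bzr1-D and rose with the replicate block (0.0075).

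**Figure D3:**
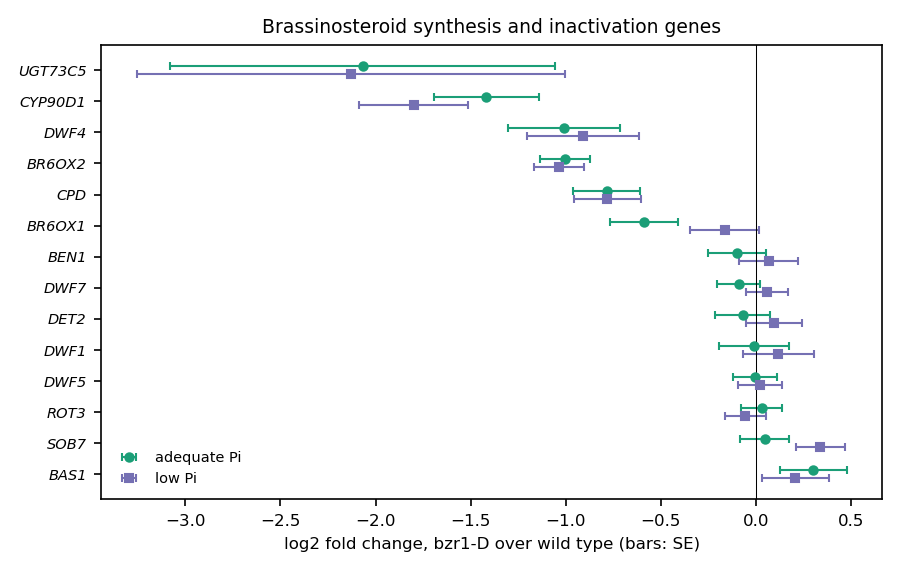
Log2 fold change of bzr1-D over wild type for the 14 genes of the brassinosteroid synthesis and inactivation list, with circles for adequate Pi, squares for low Pi and bars for the SE. BR6OX2 lies at -1.0 and -1.04 and CYP90D1 at -1.42 and -1.80.

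At low Pi, genes of brassinosteroid synthesis, Pi transport and lipid remodelling differed between genotypes. BR6OX2 fell from 17.6 ± 1.35 CPM (SD, n = 2) in wild type to 8.60 ± 0.389 CPM in bzr1-D (adjusted p = 0.0082, edgeR's quasi-likelihood test), and CYP90D1 from 15.3 ± 3.55 to 4.37 ± 0.901 CPM (0.024). PHT1;2 rose from 2.71 ± 2.82 to 164 ± 15.3 CPM (0.0038), PHT1;3 from 0.0275 to 7.14 ± 0.777 CPM (0.0012) and PHT1;8 from 1.22 ± 0.717 to 12.3 ± 0.942 CPM (0.012). The lipid remodelling enzymes MGD3 (1.77 ± 0.787 to 7.77 ± 2.52 CPM, 0.033) and SQD2 (64.0 ± 7.92 to 119 ± 23.6 CPM, 0.043) rose. BR6OX2 lost its call without bzr1-D replicate 1 (0.065) or wild type replicate 2 (0.075), and CYP90D1 without any 1 of the 4 libraries (0.12 and 0.053 without wild type replicates 1 and 2, 0.076 and 0.145 without bzr1-D replicates 1 and 2). PHT1;8 lost its call without wild type replicate 1 (0.064) or bzr1-D replicate 1 (0.062) or 2 (0.054). MGD3 lost its call without wild type replicate 1 (0.15), bzr1-D replicate 1 (0.14) or wild type replicate 2 (0.061), and SQD2 without the same libraries (0.23, 0.15 and 0.14). In a fit on only the libraries compared, BR6OX2 (0.055), MGD3 (0.074) and SQD2 (0.13) lost their calls.

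In total, 158 genes were higher and 271 lower in bzr1-D at low Pi. DESeq2 called 248 and 421, and the replicate block gave 782 and 1041, which held all 429 of the genes called without it. The counts were 71 and 157 without wild type low Pi replicate 1, 69 and 117 without wild type replicate 2, 103 and 140 without bzr1-D replicate 1, and 80 and 139 without bzr1-D replicate 2. AT5G23830 was at least 852-fold lower and SADHU5-2 at least 115-fold higher in bzr1-D, against the floor of 3 counts per library. LPR1 was at 9.23 ± 1.66 CPM in wild type and 5.23 ± 1.48 CPM in bzr1-D (adjusted p = 0.37) and fell with the replicate block (0.0046). BRI1, the brassinosteroid receptor, had a log2 fold change of -0.33 and fell with the replicate block (0.042).

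The 3 Pi lists were higher in bzr1-D at low Pi by camera. The medians were 0.53 for Pi transport (adjusted p = 5.9e-05), 0.55 for the phosphatases (0.0019) and 0.50 for lipid remodelling (5.9e-05). Each had adjusted p = 0.36 with an estimated correlation. The Pi transport list was not tested without its members in the chromosome blocks. Within Exp 1 and Exp 2 the medians were 0.97 and 0.22 for Pi transport and 0.89 and 0.24 for lipid remodelling. Of the lipid remodelling genes, 6 were higher adjusted over the list alone, and of the phosphatases PAP12 and PS2. The brassinosteroid perception list fell (median -0.14, adjusted p = 0.040 by fry, 0.036 by camera, and 0.36 by camera with an estimated correlation). The call was lost without wild type low Pi replicate 1 (0.0711) or replicate 2 (0.0509), or without bzr1-D low Pi replicate 1 (0.0914) or replicate 2 (0.0515). The brassinosteroid synthesis list had adjusted p = 0.11 by camera and 0.040 by fry, with 3 members lower adjusted over the list alone. Touch markers moved with these lists. The touch list was lower in bzr1-D (median -0.58, adjusted p = 0.023, and adjusted p = 0.48 with an estimated correlation), with WRKY40, WRKY33, JAZ1 and JAZ10 lower adjusted over the list alone. That call was lost without wild type low Pi replicate 2 (0.0556) or bzr1-D low Pi replicate 2 (0.0515). The shoot tissue list did not pass (median 0.31, 1.07 within Exp 1 and -0.20 within Exp 2, adjusted p = 0.11), but was higher in bzr1-D without wild type low Pi replicate 2 (1.3e-05) or bzr1-D low Pi replicate 2 (0.015). Of the other lists, iron deficiency and root hair (0.0057 for both, lower) passed without bzr1-D low Pi replicate 1, auxin (0.041, lower) without wild type low Pi replicate 1 and root meristem (0.0046, higher) without bzr1-D low Pi replicate 2.

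The genotype differences at the 2 Pi levels rested on separate libraries. They correlated across genes with Pearson's r = 0.91 and Spearman's rho = 0.59, with a covariance of 0.660, and r was 0.498 without a filter on low counts. Of the called genes, 120 were higher and 220 lower at both Pi levels, where independent lists would share 1.12 and 3.49, and 0 were called in opposite directions. These overlaps were 434 and 714 with the replicate block. Leaving out 1 library at a time gave overlaps of 61 to 91 and 102 to 138. Of the 340 shared genes, 325 lay in 3 chromosome blocks, with 116 on chromosome 1 from 0 to 26 Mb, 46 on chromosome 3 from 0 to 8 Mb and 163 on chromosome 5 from 5 to 25 Mb. The chromosome blocks were drawn from these same calls. In the fit with the replicate block, 454 genes higher and 764 lower at adequate Pi lay inside them, and 116 and 166 outside. At low Pi these counts were 529 and 819 inside, and 253 and 222 outside. PHT1;2, PHT1;3, PHT1;8, CYP90D1 and LPR1 lie inside the 3 chromosome blocks, whereas BR6OX2, MYB55, CLE2, MGD3 and SQD2 lie outside. AT5G23830, AT5G35965 and AT3G03855, given above as bounds against the floor, lie inside as well. Of the other list members named for a genotype difference, PHT1;1, BR6OX1, RSL4, LRL3, BEE1, LHCA3 and JAZ1 also lie inside. DWF4, CPD, PAP12, PS2, BRI1, WRKY40, WRKY33 and JAZ10 lie outside. Within 1 Mb of BZR1, 470 genes were tested and 0 were called at both Pi levels.

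**Figure D4:**
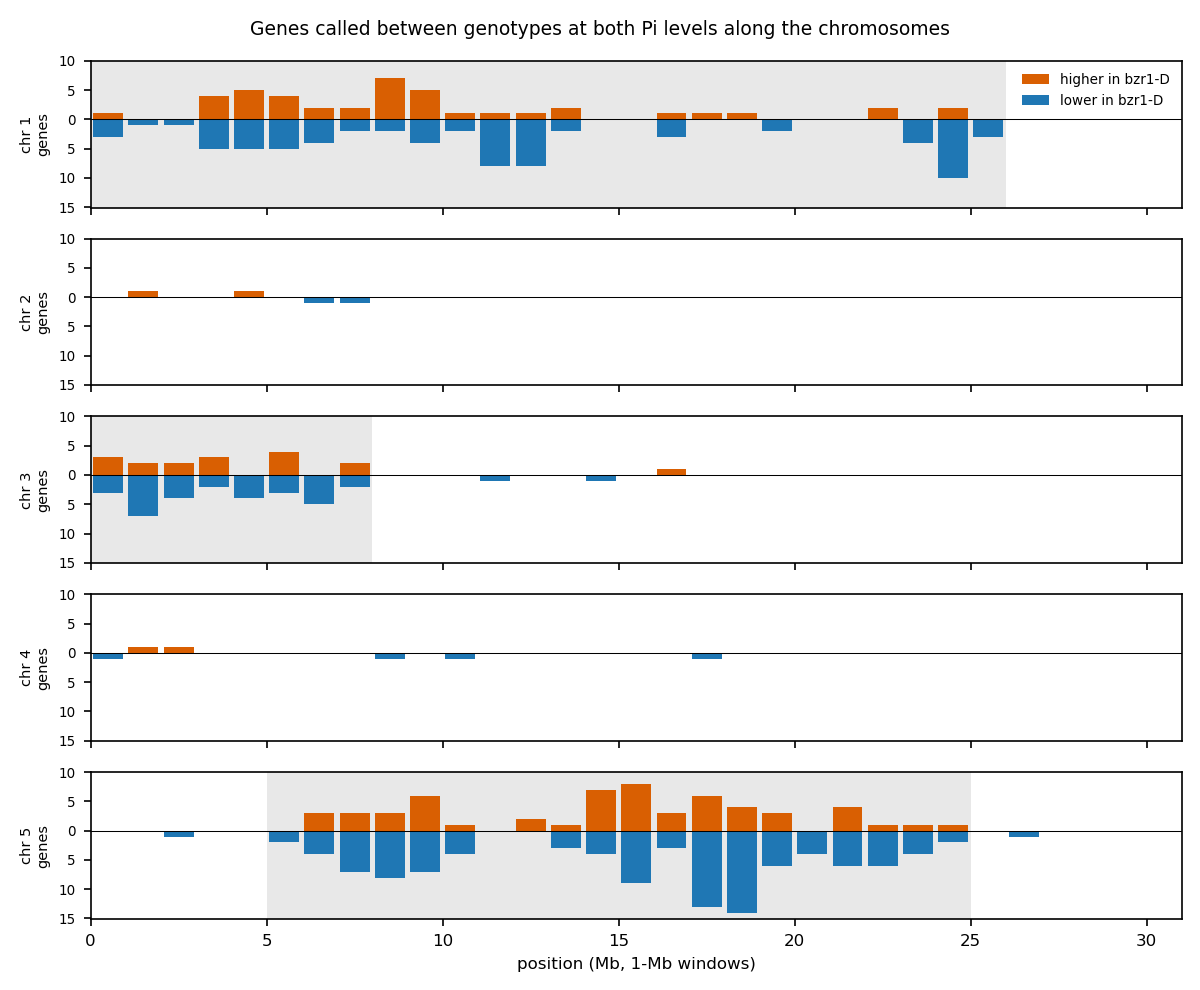
Number of genes called between bzr1-D and wild type at both Pi levels in windows of 1 Mb along the 5 chromosomes, with genes higher in bzr1-D above and genes lower below each line. Grey marks the 3 blocks on chromosomes 1, 3 and 5, which hold 325 of the 340 genes.

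**Figure D5:**
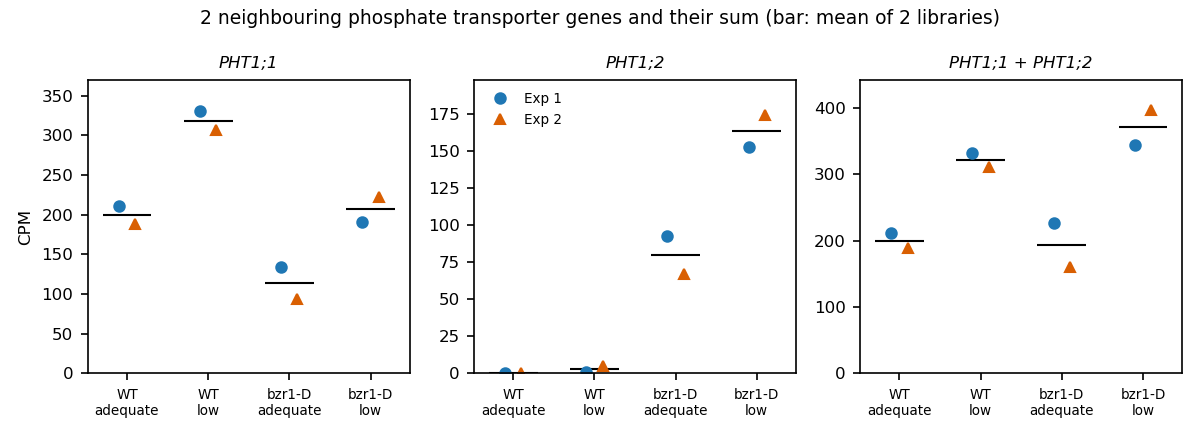
CPM of PHT1;1, PHT1;2 and their sum in the 8 libraries, on axes that start at 0, with circles for Exp 1, triangles for Exp 2 and a line for the mean of 2. PHT1;2 averaged 0.211 and 79.9 CPM in wild type and bzr1-D at adequate Pi, and PHT1;1 199.9 and 114 CPM.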

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

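Of the tests weighed in this part, the one on members outside the chromosome blocks was chosen before its result was seen, and the other 2 only after. The results in this part are 9 gene lists whose response to low Pi differed between bzr1-D and wild type by camera with a preset correlation. None of the 9 differed with an estimated correlation, where adjusted p ranged from 0.389 to 0.431, and no single gene differed by edgeR's quasi-likelihood test (159 genes with unadjusted p under 0.05, and 0 called by DESeq2 and by limma-voom).

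The membrane lipid remodelling list responded more in bzr1-D, with a median difference of 0.55 on the log2 scale and an adjusted p of 7.494e-10, and MGD3 and SQD2 were among its members with the same sign within Exp 1 and Exp 2. A weak response of wild type low Pi replicate 1 as the only source stays open. Without that library the median difference kept its sign but was lower, at 0.2903. That fit leaves a group with 1 library, so the spread of this value cannot be judged. Segments of another strain in the bzr1-D line, described under the other observations, stay open. The 6 members outside the chromosome blocks had a median difference of 0.5806, which met the rule fixed beforehand for arguing against local effects of segments. That rule set no limit on p, and the fry p was weighed in addition. It was 0.046, and 0.068 with the replicate block. Effects of a segment on genes elsewhere were not tested. An effect of the bzr1-D genotype may remain, but limma's fry, with the replicate block, gave 0.08677 for this list alone and the lower of the 2 medians within an Exp number was 0.2073, so it cannot be told apart from a chance difference of 2 libraries per group. Growth and Pi status of the plants were not tested.

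Of the other lists, root hair genes responded more in bzr1-D (median difference 0.41, adjusted p = 8.358e-05). They lost the call without bzr1-D low Pi replicate 1 or adequate Pi replicate 2. Their median log2 fold change of bzr1-D over wild type was -0.71 at adequate Pi and -0.17 at low Pi. The larger response thus started from a lower level and did not bring the list above wild type. Phosphatases and nucleases responded more (0.28, adjusted p = 1.254e-04), with a lost call without wild type low Pi replicate 1 (0.0787) or bzr1-D adequate Pi replicate 2 (0.0516). Auxin genes responded less (-0.10, adjusted p = 0.003205), and lost the call without wild type adequate Pi replicate 1 (0.252), wild type low Pi replicate 2 (0.604), bzr1-D adequate Pi replicate 2 (0.123) or bzr1-D low Pi replicate 2 (0.0585). Flavonoid genes responded more (0.36, adjusted p = 0.003205), and lost the call without wild type adequate Pi replicate 1 (0.191), bzr1-D low Pi replicate 1 (0.721), wild type low Pi replicate 2 (0.182) or bzr1-D adequate Pi replicate 2 (0.742). Shoot tissue genes responded less (-0.64, adjusted p = 0.003205), with 0.84 within Exp 1 and -1.50 within Exp 2. That call was lost without bzr1-D adequate Pi replicate 1 (0.205), wild type adequate Pi replicate 2 (0.178) or bzr1-D low Pi replicate 2 (0.242), and turned to a higher response without wild type low Pi replicate 2 (0.746). Pi transport genes had a median difference of 0.05 (adjusted p = 0.03456), and brassinosteroid perception genes -0.13 (adjusted p = 0.03456). Pi transport kept its call in 3 of 8 fits without 1 library and brassinosteroid perception only without wild type adequate Pi replicate 2, with adjusted p from 0.0923 to 0.308 otherwise. Suberin genes responded more (0.13, adjusted p = 0.04665) and lost the call in 6 of the 8.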

How the results depend on the processing

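The fits that join the replicate block with DESeq2, limma-voom, an estimated correlation or a left-out library, and the counts outside the chromosome blocks, were added after seeing the data. All other alternatives were planned. Over all settings, 2939 values of named genes kept their direction and side of the threshold, 98 lost the call and 88 gained one. Another 30 changed direction with no call in either fit, and 0 changed direction with a call in either. For gene lists these numbers were 484, 153, 33, 70 and 8. Other size factors and the filter at 1 CPM left every count of called genes within 1.5 times of the reported one.

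The Pi response in wild type, with 0 genes called higher and 0 lower, had 28 higher by DESeq2, 13 and 4 with the replicate block, and 53 and 18 by DESeq2 and 7 and 2 by limma-voom with the replicate block. Leaving out 1 library gave 0 to 10 higher and 0 lower, and with the replicate block 0 to 171 higher and 0 to 58 lower. In bzr1-D, with 0 and 0, DESeq2 gave 20 higher, the replicate block 4 higher and DESeq2 with the replicate block 49 higher and 2 lower, and left-out libraries gave 0 throughout and 0 to 41 higher and 0 to 9 lower with the block. For bzr1-D against wild type at adequate Pi (143 and 261), DESeq2 gave 220 and 411, the replicate block 570 and 930, a threshold of 0.01 73 and 120, genes outside the chromosome blocks 7 and 12, and left-out libraries 69 to 74 and 102 to 147, or 230 to 276 and 370 to 579 with the block. At low Pi (158 and 271), these were 248 and 421, 782 and 1041, 72 and 130, 13 and 16, and 69 to 103 and 117 to 157, or 499 to 972 and 686 to 962 with the block. A fit on only the libraries compared gave 98 and 175 there, and DESeq2 with the replicate block 689 lower. Outside the chromosome blocks, the replicate block gave 116 and 166 at adequate Pi and 253 and 222 at low Pi. For the difference of the Pi responses (0 and 0), DESeq2 with the replicate block gave 1 higher, and left-out libraries 0, or 0 to 11 higher and 0 to 21 lower with the block. The cause was not tested.

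The correlation of the Pi responses was 0.060 without a filter on low counts and 0.16 to 0.33 without 1 library, and genes higher in both numbered 8 by DESeq2 and 2 with the replicate block. The correlation of the genotype differences was 0.498 without the filter and 0.806 to 0.894 without 1 library. Genes called in both numbered 434 higher and 714 lower with the replicate block, 335 lower by DESeq2, 66 and 108 at 0.01, and 61 to 91 and 102 to 138 without 1 library.

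For the Pi transport, phosphatase and lipid lists in wild type, adjusted p was 0.227, 0.355 and 0.355 by fry, 0.163, 0.179 and 0.179 with an estimated correlation and 0.313 for each when the replicate block was added. Without 1 library it ranged from 5.1e-16 to 8.7e-08, from 5.4e-09 to 0.0050 and from 4.9e-09 to 0.016. In bzr1-D it was 0.0530 by fry for the first and second list, and 0.127, 0.182 and 0.127 with an estimated correlation and the replicate block. Without 1 library it ranged from 1.1e-20 to 6.0e-09, from 9.7e-12 to 7.0e-09 and from 3.0e-24 to 4.8e-13. For the difference of the Pi responses, the 3 lists had 0.915, 0.910 and 0.497 by fry, 0.431, 0.407 and 0.389 with an estimated correlation, and 0.618, 0.548 and 0.387 with the replicate block too. Pi transport had 0.0832 with the replicate block. Without 1 library the ranges were 2.7e-06 to 0.742, 5.1e-10 to 0.0787 and 7.1e-16 to 1.4e-04. Brassinosteroid synthesis genes at adequate Pi had 0.429 with an estimated correlation, 0.804 with the replicate block too, and 0.0040 to 0.037 without 1 library. At low Pi they had 0.0403 by fry and 0.051 to 0.305 without 1 library. The cause was not tested.

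Lists with a call in either fit turned direction without 1 library in 8 cases, and the lowest and highest adjusted p over left-out libraries are given beside them. In 61 further cases a list turned direction with no call in either fit, and those are not listed. In wild type these were auxin without low Pi replicate 2 (0.859, from 1.02e-04 to 0.859), shoot tissue without low Pi replicate 2 (0.374, from 6.32e-09 to 0.374) and the meristem without adequate Pi replicate 2 (0.00412, from 2.87e-04 to 0.186). In bzr1-D they were the meristem without low Pi replicate 2 (0.0107, from 1.12e-04 to 0.576) and flavonoids without adequate Pi replicate 2 (0.0355, from 0.00968 to 0.0545). In the difference they were Pi transport without wild type low Pi replicate 1 (0.563), the meristem without wild type adequate Pi replicate 2 (0.0332, from 5.22e-04 to 0.932) and shoot tissue without wild type low Pi replicate 2 (0.746, from 7.72e-09 to 0.746). The cause was not tested.

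The replicate block took no call from a named gene and changed no other list call by camera than those given here and in the report. Of the limits set by depth, a gene at 1 CPM rested on 15.9 counts or more. Counts with a batch effect were simulated at the real library sizes, with 2 libraries per group. Without the block, 33% of 2-fold Pi responses in wild type and 3% of 2-fold differences between Pi responses were called. With it, 91% and 72% were called. False calls numbered 1 and 0 without the block, and 29 and 19 with it. A larger share of the calls made with the block was therefore false.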

Other observations

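The tests on strain segments and on shared reads were chosen before their results were seen, and the other 3 tests in this part only after.

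Outside the 3 chromosome blocks, 15 genes were called between bzr1-D and wild type at both Pi levels, 5 higher and 10 lower, and they were named after their values were seen. In the fit with the replicate block, 116 genes were called higher and 166 lower there at adequate Pi, and 253 and 222 at low Pi. MYB55 was at 20.03 ± 1.71 CPM (SD, n = 2) in wild type and 4.05 ± 0.127 CPM in bzr1-D at low Pi, and kept its call at either Pi level whichever library was left out. CLE2 was at 6.74 ± 0.127 and 1.25 ± 0.317 CPM at low Pi. BLH2, a homeodomain protein, was at 7.34 ± 0.359 and 1.79 ± 0.336 CPM at adequate Pi, and its adjusted p there was 0.0705 and 0.0928 without wild type replicates 1 and 2 and 0.111 and 0.175 without bzr1-D replicates 1 and 2. At low Pi BLH2 lost its call without wild type replicate 2 (0.0855) or bzr1-D replicate 2 (0.0907). AT4G04223 went the other way, from 0.433 ± 0.104 to 12.2 ± 0.390 CPM at adequate Pi, and kept its call whichever library was left out. At2NC028310, a non-coding transcript, was at least 17.3-fold lower at adequate Pi and at least 18.7-fold lower at low Pi against the floor of 3 counts per library.

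Genes called between the genotypes at both Pi levels gathered on parts of chromosomes 1, 3 and 5, in blocks that were defined from these calls, and 115 of the 325 genes inside were higher in bzr1-D. These calls were spread less evenly than random draws of tested genes, as 57 of 121 windows held no such gene, where the draws gave at most 30. That count was chosen after the gathering was seen, and the draws treat neighbouring genes as independent. It therefore cannot decide on a gain of function of BZR1 as the whole cause. Segments of another strain in the bzr1-D line cannot be told apart from other causes, since strain variants and their effect on mapping were not tested. Genes called at neither Pi level were lower in bzr1-D inside the blocks than outside by a median of -0.01493 on the log2 scale (share of circular shifts as low 0.01653), but this decides nothing, as the blocks and these genes were both chosen by the calls and the median absolute deviation was 0.208 inside and 0.143 outside. An effect of BZR1 stays open, as the 8 list genes of brassinosteroid synthesis (5, BR6OX2 among them) and inactivation (3) outside the blocks had medians of -0.4191 or lower and a fry p of 0.009215 or less at both Pi levels, with 6 of the 8 lower at adequate Pi and 5 at low Pi.

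PHT1;2 was higher and PHT1;1 lower in bzr1-D, and both lie in the block on chromosome 5. Reads shared between the paralogs stay open, since 70.43% of the 50-base stretches of PHT1;2 exons occur in PHT1;1 with at most 2 mismatches. That share was measured in the reference sequence alone, so it cannot tell why the counts differ between the genotypes. A change of 2-fold or more in the summed transcript is argued against, since the bounds of the 95% interval of the summed log2 fold change lay within 0.7113 of 0 at both Pi levels (smaller unadjusted p = 0.295 by edgeR's quasi-likelihood test). The sum had log2 fold changes of -0.05 ± 0.18 (SE) at adequate Pi and 0.21 ± 0.18 at low Pi. A smaller change in the sum stays open, and so does whether each transporter differs in truth between the genotypes.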
